A study of Mus musculus with 62 samples.

How the data were processed

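The read counts used here are those deposited by the authors, 1 file per library for 62 libraries, and no reads were aligned again. Per the submitters' processing notes, reads were handled with cutadapt 1.9.1, TopHat2 2.0.11, Bowtie2 2.2.7 and HTSeq 0.9.1 on genome build GRCm38.p6, while the parameters and the gene annotation are not given in the sources used here. Per the labels' protocols, libraries were made from the 3′ ends of amplified cDNA from 1 ng of total RNA. Per the file headers, each file gives a read count and an RPM value. Each file had 36038 rows, of which 35914 were nuclear genes with counts, 13 mitochondrial genes, 96 spike-ins and 5 transgene sequences; 10 genes were blank in every library and were left out. The deposited RPM matched the count over the reads of nuclear genes, with a largest relative difference of 4.9e-06 among values of 10 RPM or more.

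The plan, written beforehand, was limma on log2(RPM + 1) unless the values were counts. Because the files hold raw counts, edgeR became the main test and limma an alternative, a departure that the plan allowed for. Nuclear genes with at least 5 RPM in at least 2 libraries were kept (16008 genes over all libraries, 12106 over the cultured lines). Library sizes were scaled by TMM, and quasi-likelihood fits with robust estimation (edgeR 4.0.16 in R 4.3.3) used 1 coefficient for each of 31 groups, so that a stage is the mean of its time points. The 3 comparisons between line sets used reads summed by line, with 12 columns. A gene was called at an adjusted p below 0.05 (Benjamini-Hochberg) and an absolute log2 fold change of at least 1. Fold changes are differences of mean log2 values over time points, so a time point near 0 reads weighs heavily in them and they can part from the ratio of mean CPM; levels are therefore printed in preference. Where a side had 0 reads the fold is given as a bound, from a floor of 3 reads over that side.

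The 23 lists were fixed beforehand: PGC and pluripotency, core germ cell, piRNA and de novo methylation, undifferentiated, differentiating, meiotic prophase, spermatid, proliferation, CDK inhibitors, Sertoli, Leydig, stromal, endothelial, macrophage and blood, imprinted, glycolysis, oxidative phosphorylation, immediate early, p53 targets, interferon, cholesterol, DNA methylation and chromatin, and GDNF and FGF response. They were tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM with a prior count of 2, with an estimated correlation and with fry, and p-values were adjusted over all lists of a comparison. Counts "adjusted over the list alone" take the edgeR p-values of the measured members only. Some lists share members, so their results are not independent. Bcl6b, Lhx1 and Egr2, for example, are in the undifferentiated and the GDNF and FGF lists, and Mael and Gtsf1 in the core germ cell and piRNA lists. Nearest stages are Pearson correlations of log2(RPM + 1) over the 1000 genes with the largest variance between in vivo time points.

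Named genes follow a rule written before the data were examined: the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 20 RPM on the higher side and no overlap between libraries (or lines) of the sides, without genes known only by a number; up to 4 called members of each described list with the largest change, or up to 2 as values where fewer than 2 were called; and always Ddx4, Prdm1, Dppa3, Cd9 and Acr. Acr did not reach the filter, and some genes that the rule selects are not reported here. Genes with levels by time point, and C1qa, Inha and Dcn where no list names them, were chosen after their values were seen. The choice of comparisons, tests, lists, thresholds and most alternative settings was made before the data were examined. DESeq2 1.42.0 and limma served as alternative tests, with pseudocounts of 0.5, 1 and 5 and a filter of 20 RPM.

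The main test was tried on simulated counts with real gene means and library sizes, the spread between libraries of a group, and 200 changed genes. Spread between lines was not simulated, so the rates below do not cover it in the 3 comparisons between line sets. A true log2 change of 2 was called in 76.1% of genes for d4c5 against d4 and in up to 100% elsewhere, and a change of 3 in 92.4% to 100%. A change of exactly 1 was called in 28.4% to 58.2%, and unchanged genes in 0.01% to 0.07%. Of 100 lists without change at most 2 had an unadjusted camera p below 0.05 at the preset correlation. The simulated genes were drawn independently, so this does not measure false calls for lists whose genes vary together. The 2 libraries of a group differed beyond sampling noise, with a chi-squared over its degrees of freedom of 1.53 to 16.7. The labels do not say that they come from separate cultures or animals. Outside the 3 comparisons between line sets, each p measures the spread between the 2 libraries of a group, which may be technical. It does not measure the spread between time points. In the 3 comparisons between line sets p measures the spread between lines.

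Libraries ranged from 1404261 to 4485280 nuclear reads, 13532 to 23630 genes with a read, 3.29% to 16.7% mitochondrial reads and 0.216% to 7.24% ERCC reads. The relative reads of 34 spike-ins put 10 in vitro libraries apart (the first library from d4c5 to m14, and the second of m12 and m14), with a median of 4.75% mitochondrial reads against 9.98%. Within in vitro groups from m0 to m14 the difference between first and second library was shared between groups (correlations from 0.099, median 0.432), which was not so in vivo (−0.159 to 0.147). Fits with that profile as a covariate, without those libraries, without P1, and without m0 and m3 were added after the data were seen.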

Results

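The series held 62 mouse libraries in 31 groups of 2, each read from the 3′ ends of transcripts in 1 ng of total RNA, with 1493521 to 5662007 counted reads per library. In vivo, male germ cells carrying Ddx4-RFP were sampled as prospermatogonia at E14.5, E15.5, E16.5, E17.5 and E18.5 (n = 10) and as spermatogonia at P0, P1, P3, P5 and P7 (n = 10). In vitro, PGC-like cells (d4 and d4c5, n = 4), prospermatogonia-like cells (m0, m3, m5 and m7, n = 8) and spermatogonia-like cells (m10, m12 and m14, n = 6) were sampled along a culture in which PGC-like cells meet E12.5 testis somatic cells in reconstituted testes. The cultured germline stem cell line GSC1 (n = 2) stood beside GSC-like cell lines W1 to W4 (n = 8), S1 to S4 (n = 8) and 3 W lines with the prefix 16 (n = 6). What W, S and 16 stand for is not given in the sources used here.

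The title of the series asks whether the whole of male germ cell development can be rebuilt from pluripotent stem cells, and the groups allow that question to be put stage by stage. Spermatogonia against prospermatogonia showed which genes differ between the fetal and the postnatal time points in vivo, the same step in vitro showed which of them change in culture, and the difference between these steps showed where the culture departs. Direct comparisons of like stages asked how far the cells differ. Strain, reporter genotype and culture differ together between the in vivo and the in vitro cells, so their effects cannot be told apart. GSC-like cells were set against m14, the stage from which the labels say the lines were derived, against GSC1, and by line set. GSC1 was set against P7, and strain labels differ in this comparison and in that with m14. Levels below are TMM-scaled CPM as mean ± SD over libraries. The words "rose" and "fell" are kept for genes that passed the edgeR test with a change of at least 2-fold.

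The vasa gene Ddx4, a lasting mark of germ cells, climbed in culture from 15.9 CPM at d4 to 55 at d4c5, 162 at m0, 405 at m3 and 601 at m5 (n = 2 each). It then held at 487 at m14, against 581 to 1131 in vivo. Dppa3, a gene of primordial germ cells, stood at 2223 CPM at E14.5 and 44.2 at E16.5. In culture it stayed at 1571 at m0, 1824 at m3 and 1097 at m5 before it reached 79.9 at m7 and 16.2 at m10. Dnmt3l, the cofactor of de novo DNA methylation, was at its highest at E15.5 (810 CPM) in vivo and at m7 (404) in culture, with 0.842 at m0 and 0 at m3. Spocd1, which directs that methylation to transposons, followed it with 544 CPM at E16.5 and 482 at m7, against 0 at m0 and 1.27 at m3. Gfra1, the receptor of GDNF on stem spermatogonia, went from 18.3 CPM at E18.5 to 91.1 at P0 and 279 at P1, and from 6.64 at m7 to 72.3 at m10 and 124 at m14. The proliferation marker Mki67 was low from E14.5 (23.4 CPM) to P0 (29) and high at P3 (311). In culture it was 344 at m0, 64.4 at m7, 65.6 at m10 and 254 at m14. These genes were chosen after their values were seen, and no test is attached to single time points.

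**Figure D1:**
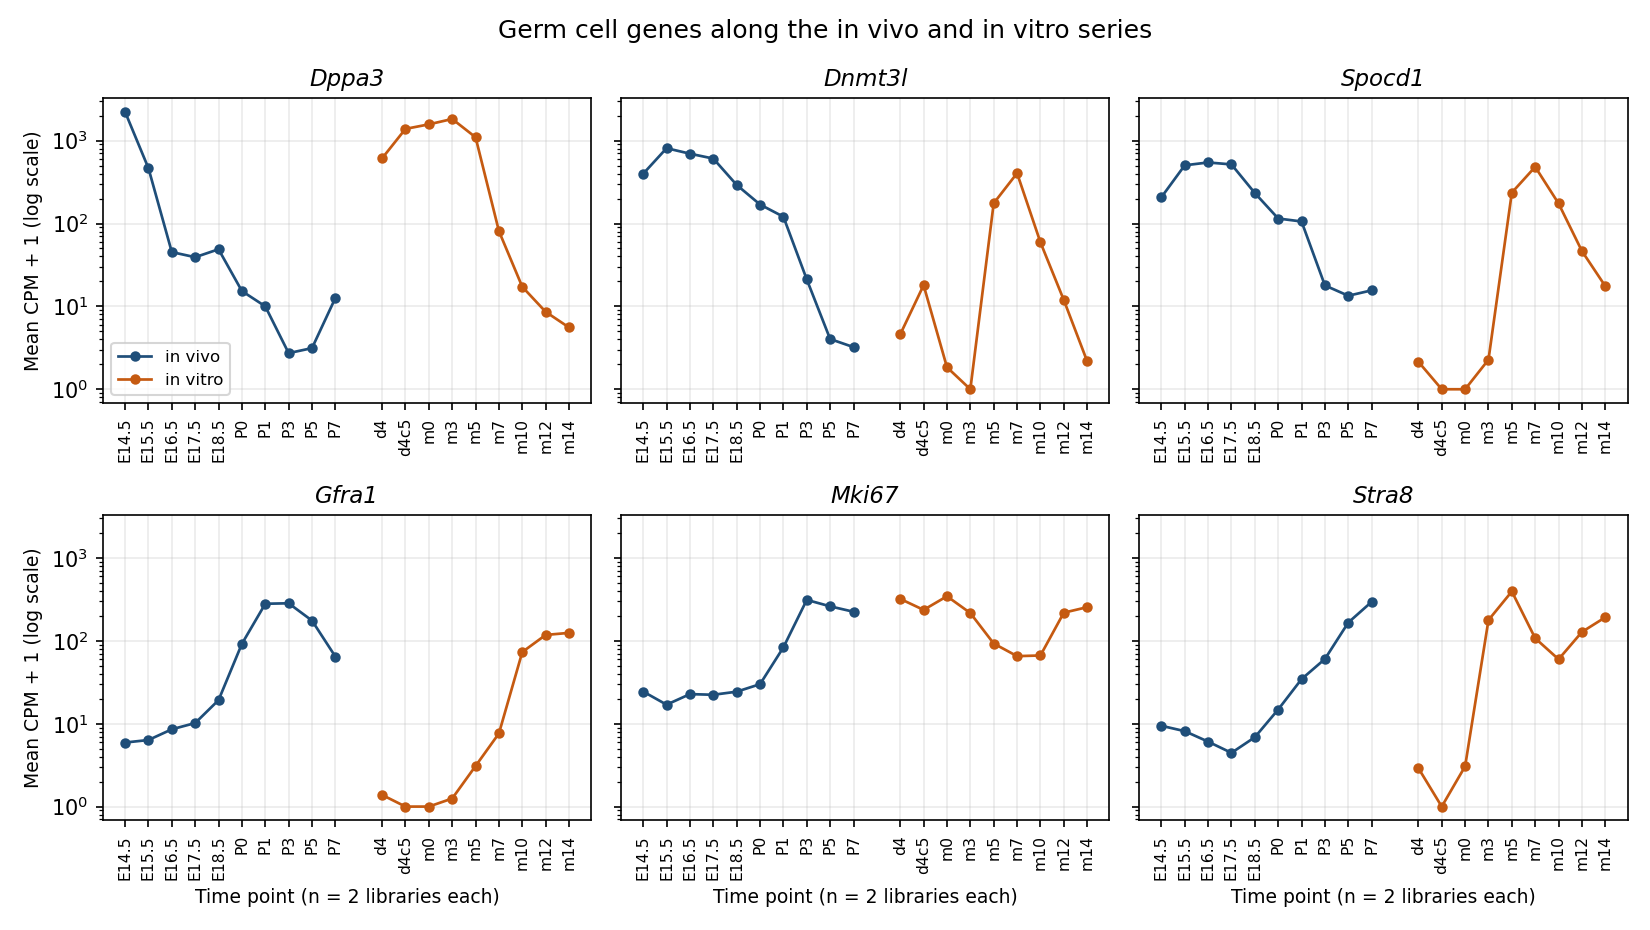
Mean levels of 6 germ cell genes at each time point in vivo and in vitro (n = 2 libraries per point, log scale of CPM + 1). Dnmt3l reached 810 CPM at E15.5 and 404 at m7, and Gfra1 reached 283 CPM at P3 and 124 at m14.

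Over the 1000 genes that varied most between the in vivo time points, d4, d4c5, m0 and m3 lay closest to E14.5 but with Pearson correlations of only 0.5, 0.479, 0.513 and 0.584 (mean of 2 libraries). The m5 cells lay closest to E14.5 (0.808), m7 to E15.5 (0.733, with 0.711 to E16.5), m10 to P3 (0.781), m12 to P3 (0.859) and m14 to P5 (0.864). GSC1 (0.862) and every GSC-like line lay closest to P5. Genes are not independent replicates, so these correlations carry no p, and with Spearman correlations 21 of 42 libraries kept the same nearest stage. Over all genes past the filter 33 did, and there every library of d4, d4c5 and m0 lay closest to P5, so their place at E14.5 depends on the choice of genes. The libraries of a pair parted at m3, where the second was nearest to P7 (0.581), and at m10, where the second was nearest to P1 (0.771).

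At the step from prospermatogonia to spermatogonia in vivo, genes of the spermatogonial stem cell rose: Gfra1 from 9.06 ± 5.33 to 178 ± 96.8 CPM, Foxc2 from 2.83 ± 3.72 to 82.4 ± 51.7, Lhx1 from 6.12 ± 5.18 to 67.9 ± 49.8 and Egr2 from 7.45 ± 4.08 to 75.7 ± 34 (n = 10 and 10). Genes of the GDNF and FGF response rose with them, including Etv4 (3.2 ± 2.75 to 58.7 ± 57.3) and the feedback inhibitor Spry4 (1.35 ± 0.905 to 22.4 ± 14.3). Genes of differentiation and division rose too. Stra8, the target of retinoic acid, went from 6 ± 2.02 to 113 ± 111 CPM, Sohlh2 from 10.6 ± 4.8 to 75 ± 29.1 and Dmrt1 from 64.4 ± 35.4 to 402 ± 165. Mki67 rose from 21.2 ± 4.08 to 181 ± 115 and Rrm2, a subunit of ribonucleotide reductase, from 5.47 ± 1.51 to 70 ± 43.1. Some genes of fetal methylation fell: Dnmt3l from 560 ± 202 to 62.7 ± 72.4 CPM, Spocd1 from 400 ± 159 to 52.5 ± 49.1, the piRNA effector Piwil4 from 527 ± 298 to 66.9 ± 19 and the H3K4 demethylase Kdm1b from 983 ± 483 to 176 ± 95. Dppa3 fell from 563 ± 900 to 7.77 ± 5.74 CPM and Utf1 from 319 ± 159 to 31.1 ± 18.1. Ddx4 did not pass (log2 fold change −0.22, 807 ± 212 and 676 ± 78.3 CPM). Uhrf1, which maintains methylation in dividing cells, rose from 10.5 ± 4.57 to 103 ± 56.6 CPM, and Cd9, a surface marker of these cells, rose from 119 ± 70.4 to 256 ± 124.

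In edgeR, 1799 of 16008 genes rose and 3449 fell in this step. Without both P1 libraries, an alternative added after the data were seen, 1783 rose and 3847 fell. With all libraries the deposited RPM scaling would shift every fold by 0.148 log2, and gave 2339 rising and 3014 falling. Under limma with a pseudocount of 5 the balance turned, with 1197 rising and 794 falling.

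Lists of genes fixed beforehand put these changes in context, and adjusted over the list alone no count of this step changed. Of 28 genes of undifferentiated spermatogonia 15 rose and 3 fell (camera adjusted p = 2.93e-05, but adjusted p = 0.056 with an estimated correlation). Of 14 differentiation genes 10 rose, among them Dmrtb1, and none fell (adjusted p = 1.04e-05). Of 18 GDNF and FGF response genes 13 rose (adjusted p = 7.34e-09). Of 29 proliferation genes 16 rose, with Aurkb going from 14.1 ± 6.47 to 92 ± 62.8 CPM (adjusted p = 2.69e-14). Of 19 genes of cholesterol synthesis 7 rose (adjusted p = 2.71e-05), among them Lss (22.5 ± 15.3 to 94.7 ± 32.4 CPM). Of 44 genes of oxidative phosphorylation 8 rose (adjusted p = 0.000809, and adjusted p = 0.241 with an estimated correlation).

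Among lists that leaned downward, 2 of 20 PGC and pluripotency genes rose and 12 fell (adjusted p = 0.00368). Of 22 genes of the piRNA pathway and de novo methylation 2 rose and 8 fell (adjusted p = 0.00329, but adjusted p = 0.128 with an estimated correlation). Of 20 core germ cell genes 3 rose and 6 fell without a shift of the list (adjusted p = 0.824), with the bromodomain gene Brdt falling from 365 ± 70.4 to 81.4 ± 52.3 CPM and Taf7l rising from 132 ± 33.1 to 432 ± 147. Of 34 meiotic prophase genes 7 rose and 3 fell (adjusted p = 0.224), Syce2 reaching 282 ± 101 CPM from 56.5 ± 24.3, and of 8 spermatid genes Crisp2 alone fell. Of 21 genes of DNA methylation and chromatin 4 rose and 5 fell, and of 30 imprinted genes 2 rose and 8 fell (Grb10 from 290 ± 182 to 94.1 ± 107 CPM). Of 10 interferon response genes 1 rose and 5 fell, and of 18 glycolysis genes 1 rose and 2 fell. Immediate early and stress genes gave 7 rising and 3 falling of 16 (Egr1 from 38.6 ± 13.3 to 179 ± 71 CPM). Of 12 p53 target genes 4 rose, and of 6 genes of CDK inhibitors Cdkn1a rose and Cdkn1b fell.

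Transcripts of somatic cells accompanied the prospermatogonia libraries. The Leydig gene Cyp17a1 stood at 16.9 ± 10.1 CPM there and 0.277 ± 0.458 in spermatogonia, and all 5 Leydig markers fell (adjusted p = 0.00842, but adjusted p = 0.128 with an estimated correlation). The collagen gene Col3a1 fell from 80.3 ± 48.9 to 15.9 ± 9.96 CPM, with 10 of 16 stromal markers falling (adjusted p = 0.00842, and 0.128 with an estimated correlation), and the Sertoli gene Sox9 fell from 25.2 ± 9.92 to 6.92 ± 6.41, with 8 of 17 Sertoli markers falling (0.00941, and 0.199 with an estimated correlation). Of 9 endothelial markers 6 fell (0.0477, and 0.155 with an estimated correlation). Of 14 macrophage and blood markers 4 fell, all of them haemoglobin genes such as Hba-a1 (31.2 ± 15.6 to 6.83 ± 6.77 CPM). Reads of Hbb-bs and Hbb-bt may have been split by counting, and their levels are uncertain.

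In culture the stem cell genes rose as well. Gfra1 went from 2.25 ± 3.1 CPM in prospermatogonia-like cells to 104 ± 30 in spermatogonia-like cells (n = 8 and 6), its co-receptor Ret from 9.96 ± 7.38 to 168 ± 56 and Foxc2 from 0.713 ± 1.32 to 53.2 ± 13.8. The GDNF target Bcl6b rose from 5.03 ± 5.05 to 81.4 ± 20.4, Zbtb16 from 1.81 ± 2.57 to 26.7 ± 9.55 and Nkx2-3 from 1.82 ± 2.7 to 36.3 ± 13.7. So did Ccnd1 from 4.19 ± 3.78 to 66.7 ± 20.2 CPM and Ccnd2 from 17.1 ± 10.1 to 139 ± 62.6. Pluripotency genes that early germ cells share fell: Dppa3 from 1143 ± 764 to 9.46 ± 6.04 CPM and Nanog from 72.7 ± 75.3 to 0.731 ± 1.13. So did Utf1 from 490 ± 248 to 44.8 ± 35.2, Gdf3 from 46.4 ± 45.3 to 1.16 ± 0.552 and the 5-methylcytosine oxidase Tet1 from 91.1 ± 83.4 to 4.77 ± 5.32. Mup6 had 332 reads in prospermatogonia-like cells and 0 in spermatogonia-like cells, a fall of at least 95.6-fold, though its large gene family makes the assignment of reads uncertain. Uhrf1 rose from 22.1 ± 13.6 to 91.3 ± 23 CPM, and Ddx4 did not pass (433 ± 199 and 484 ± 98.8 CPM).

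Macrophage transcripts appeared at the same step: the lysozyme gene Lyz1 rose from 9.74 ± 17 to 268 ± 176 CPM, Tyrobp from 2.93 ± 4.33 to 61.1 ± 32.2 and the complement gene C1qa from 1.76 ± 3.55 to 41.4 ± 25.9. C1qa had 0 reads up to m5, 7.03 CPM at m7 and 56.5 at m14. Of 14 macrophage and blood markers 10 rose (camera adjusted p = 2.95e-06, but adjusted p = 0.0651 with an estimated correlation). Of 16 stromal markers 9 rose, with Dcn going from 26.3 ± 34.3 to 96.9 ± 61.8 CPM (adjusted p = 0.00198, and 0.0651 with an estimated correlation). Of 17 Sertoli markers 3 fell, among them Sox9 (16.2 ± 10.7 to 8.14 ± 6.07 CPM; adjusted p = 0.0301, and 0.328 with an estimated correlation).

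In edgeR, 2077 genes rose and 843 fell in the culture step. RPM scaling would shift each fold by 0.24 log2 and gave 2778 rising and 568 falling genes. With time points as units 523 rose and 526 fell, so the excess of risers was gone. The balance turned when m0 and m3, the earliest cultures, were left out, an alternative added after the data were seen: 1037 genes rose and 1668 fell, and 1181 genes were shared between these calls and the full set. With the spike-in profile as a covariate 2927 genes were called.

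Of 20 PGC and pluripotency genes 17 fell and none rose (adjusted p = 8.74e-19). Of 28 genes of undifferentiated spermatogonia 17 rose and 2 fell (adjusted p = 9.12e-09). Of 18 GDNF and FGF response genes 13 rose (adjusted p = 3.44e-13). Adjusted over the list alone these counts did not change. Without m0 and m3 they became 1 rising and 11 falling, 13 rising and 2 falling, and 15 rising genes. The lists of germ cell identity depended on the early cultures. With them 10 of 20 core germ cell genes rose and 1 fell (adjusted p = 2.89e-05), against 1 rising and 4 falling without them. Likewise 11 of 22 piRNA and de novo methylation genes rose with them (adjusted p = 2.18e-05), against 1 rising and 7 falling without. Of 34 meiotic genes 9 rose and 3 fell with m0 and m3, against 0 rising and 13 falling without, Spo11 falling from 60.6 ± 33.2 to 8.01 ± 7.71 CPM. None of 29 proliferation genes passed (camera adjusted p = 0.452, edgeR counts of 0), although the same list held 16 risers in vivo, and without m0 and m3 9 of them rose. Of 14 differentiation genes 7 rose and 2 fell (7 and 3 adjusted over the list alone; adjusted p = 0.000808, but 0.0796 with an estimated correlation), Dmrtb1 going from 2.59 ± 3.66 to 30.4 ± 13.9 CPM.

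Smaller shifts touched genes of stress and metabolism. Of 16 immediate early genes 4 rose, with Zfp36 going from 6.93 ± 2.51 to 27.3 ± 7.79 CPM (adjusted p = 0.0293, but 0.211 with an estimated correlation). Of 12 p53 target genes 5 rose, with Pmaip1 going from 10.4 ± 3.69 to 41.1 ± 23.5 (adjusted p = 0.0213, and 0.211 with an estimated correlation). Of 18 glycolysis genes 3 fell, with Pgk1 at 330 ± 449 and 56.1 ± 13.7 CPM (adjusted p = 0.0118, and 0.43 with an estimated correlation). None of 44 oxidative phosphorylation genes passed in edgeR, where camera gave a shift (adjusted p = 0.00644) that was lost with the estimated correlation (adjusted p = 0.399).

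**Figure D2:**
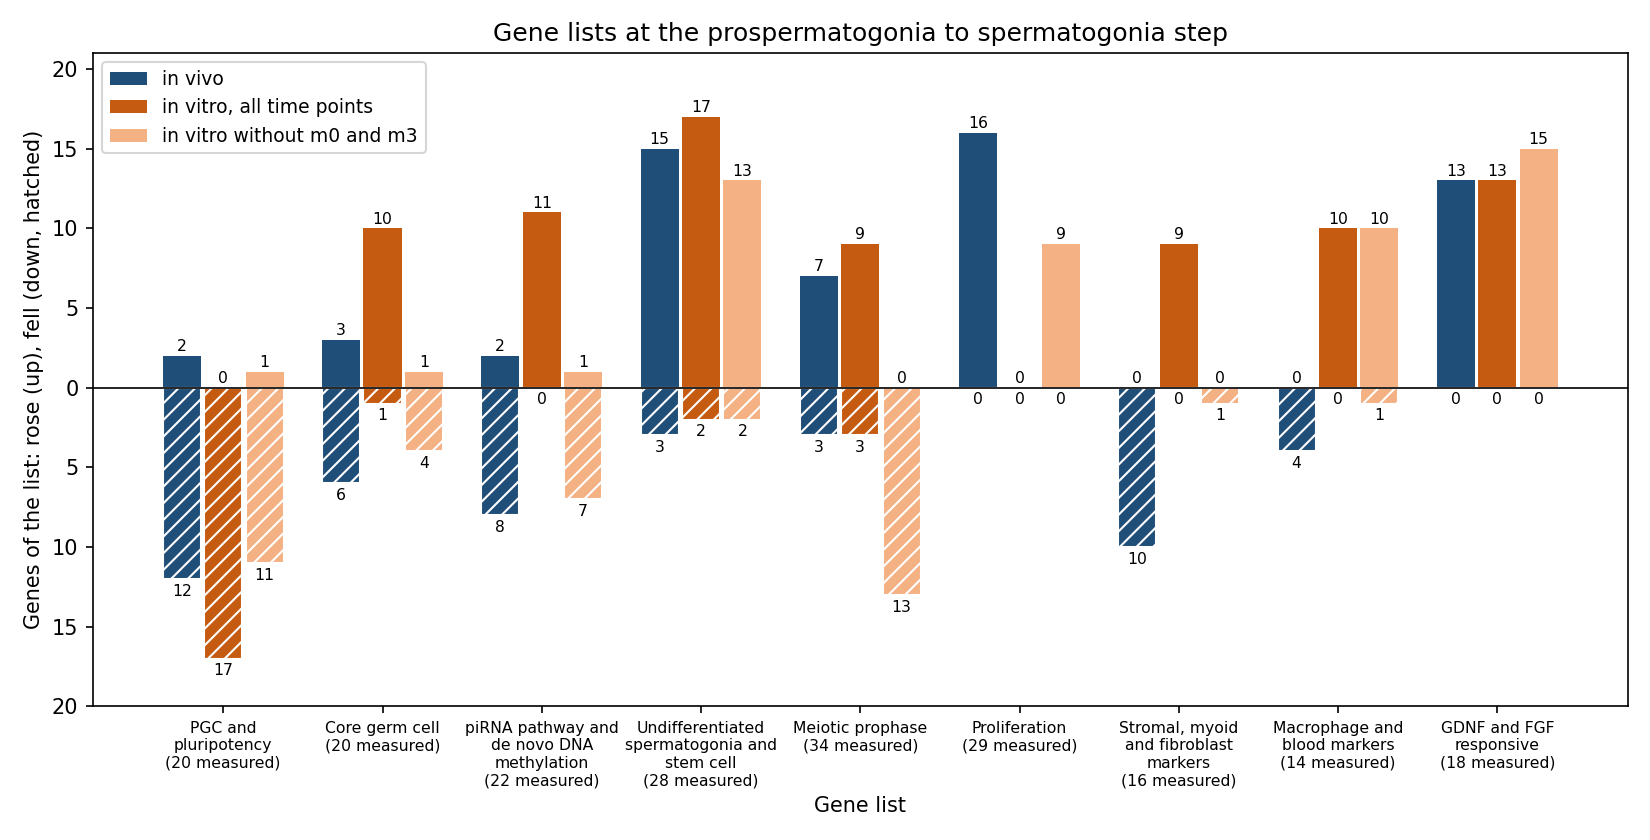
Genes of 9 lists that rose or fell at the step from prospermatogonia to spermatogonia, in vivo, in vitro and in vitro without m0 and m3. Of 29 proliferation genes 16 rose in vivo, 0 in vitro and 9 in vitro without m0 and m3, while 13, 13 and 15 of 18 GDNF and FGF response genes rose.

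Culture departed from development in several groups of genes. Spocd1 and Piwil4 fell in vivo but not in culture, where m0 and m3 held little of either (difference of log2 fold changes 6.06 ± 0.33 and 4.48 ± 0.19, SE), and Gtsf1, another piRNA gene, went the same way (3.56 ± 0.17). With m0 and m3 included, proliferation genes rose in vivo and not in culture. The differences were −2.60 ± 0.20 for Mki67, −3.11 ± 0.26 for Rrm2 and −3.83 ± 0.25 for the kinetochore gene Spc24. Without m0 and m3, 3 of 20 called proliferation genes and 0 of 14 called piRNA genes still differed between the steps. Macrophage genes came up in culture only, with 6.50 ± 1.27 for Tyrobp and 6.33 ± 0.81 for Stab1. Synaptonemal Syce2 rose in vivo alone (−2.51 ± 0.11).

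Tested as an interaction in edgeR, 2962 genes changed more upward in culture and 1247 more downward. The balance turned with time points as units, where 152 were higher and 368 lower. Of 29 proliferation genes 20 went lower (median −1.33, adjusted p = 9.41e-22). Of 22 piRNA and methylation genes 14 went higher (median 1.69, adjusted p = 1.79e-08). Of 20 core germ cell genes 11 went higher and 1 lower (median 1.33, adjusted p = 4.11e-05) and of 20 PGC genes 9 lower (median −1.27, adjusted p = 5.52e-06). Of 16 stromal markers 13 went higher (median 2.76, adjusted p = 3.76e-06). Of 14 macrophage and blood markers 5 went higher (median 6.11, adjusted p = 3.08e-08) and of 19 cholesterol genes 5 lower (median −0.85, adjusted p = 1.95e-05). Adjusted over the list alone these 7 pairs of counts were the same. Without m0 and m3 only 774 genes were higher and 457 lower, and the lists held 3 calls of proliferation genes, 1 of piRNA genes (lower), 2 of core germ cell genes (lower), 9 of stromal markers and 4 of macrophage markers. None of the 14 piRNA genes called above was called then.

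Several shifts of whole lists did not outlast an estimated correlation: differentiation genes (1 higher, 6 lower; adjusted p = 0.0441, then 0.287 with an estimated correlation), imprinted genes (12 higher and 2 lower, 13 and 2 adjusted over the list alone; 0.0441, then 0.094), glycolysis genes (1 and 3; 0.0435, then 0.587), oxidative phosphorylation genes (0 and 9; 1.79e-08, then 0.0681) and genes of DNA methylation and chromatin (3 and 8; 0.0125, then 0.156).

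Genes called in both steps mostly moved the same way. Of those higher, 493 were shared where independent calls would give 233.4. Of those lower, 490 were shared where 181.6 would be given, while 338 went in opposite directions. Across 16008 genes the Pearson correlation of the fold changes was 0.284 and the Spearman correlation 0.265, and genes are not independent replicates. Without m0 and m3 the shared sets grew to 592 (116.5) and 1274 (359.4), opposite calls shrank to 48, and the correlations were 0.669 and 0.694.

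From PGC-like to prospermatogonia-like cells, genes of the germ cell programme rose. Ddx4 rose from 35.4 ± 23.4 to 433 ± 199 CPM, the RNA-binding gene Dazl from 17.53 ± 6.53 to 708 ± 444 and the piRNA factor Mael from 10.8 ± 9.69 to 569 ± 530 (n = 4 and 8). Stra8 had 5 reads in PGC-like cells and stood at 170 ± 163 CPM in prospermatogonia-like cells. Sycp3 rose from 4.94 ± 5.13 to 204 ± 211 and Tdrd1 from 1.24 ± 1.51 to 160 ± 154. Genes of early PGCs fell: Tfap2c from 208 ± 33.3 to 51.9 ± 53.5 CPM, Nanog from 256 ± 63.5 to 72.7 ± 75.3 and Klf2 from 226 ± 65.7 to 54.8 ± 55. Also falling were the imprinted gene Phlda2 from 237 ± 61.7 to 23.8 ± 24.3 and Zscan10 from 76.3 ± 22.8 to 13.4 ± 16.1. Prdm1 fell from 130 ± 46.6 to 65 ± 49.8 and Cd9 from 299 ± 114 to 123 ± 51.9, while Dppa3 did not pass (998 ± 504 and 1143 ± 764 CPM). The large SDs follow the time points: Mael stood at 29.2 CPM at m0, 141 at m3 and 918 at m5.

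Sertoli genes rose at the same step. Cst9 went from 0 reads to 27 ± 12.2 CPM (at least 50-fold), Wt1 from 0 reads to 13.8 ± 7.16 (at least 25.5-fold) and Mro from 0 to 15.1 ± 7.03 (at least 27.9-fold). Amhr2, the receptor of anti-Müllerian hormone, stood at 36.1 ± 13.3 CPM after 2 reads. Of 17 Sertoli markers 16 rose, with a median log2 fold change of 6.19 that was 4.8 when sides without reads were set at the floor of 3 reads (adjusted p = 8.33e-11). Of 16 stromal markers 7 rose, with Col1a2 going from 1.63 ± 1.92 to 41.4 ± 44.7 CPM (adjusted p = 0.0054, but 0.0948 with an estimated correlation).

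In edgeR, 2537 genes rose and 1053 fell, and fewer were called with time points as units. Of 20 core germ cell genes 17 rose and 1 fell (adjusted p = 1.52e-15). Of 22 piRNA genes 14 rose (15 adjusted over the list alone; adjusted p = 2.91e-14). Of 34 meiotic genes 26 rose (adjusted p = 2.91e-14). Of 14 differentiation genes 8 rose and 1 fell (adjusted p = 7.29e-05) and of 20 PGC genes 1 rose and 14 fell (adjusted p = 5.48e-08). Of 29 proliferation genes 10 fell (adjusted p = 4.09e-16), with Rrm2 going from 269 ± 52 to 75.9 ± 79.3 CPM. Camera shifts lost with the estimated correlation were those of cholesterol genes (4 rose; adjusted p = 0.00719, then 0.129), imprinted genes (4 rose, 7 fell; 0.0398, then 0.0948), p53 target genes (3 fell; 0.0141, then 0.151), glycolysis genes (1 rose, 5 fell; 0.00232, then 0.389) and oxidative phosphorylation genes (2 fell; 9.86e-05, then 0.209). RPM scaling would shift the folds by 0.126 log2, and without the 10 in vitro libraries whose spike-in ratios stood apart 2909 genes were called.

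Between d4 and d4c5, several genes came down to few or 0 reads. Msx1 went from 79.7 ± 9.53 CPM to 0 reads (at least 82-fold) and Unc5b from 29.9 ± 4.41 to 0 reads (at least 30.7-fold). Id1 stood at 83.6 ± 5.78 CPM before and had 1 read after, and Hand1 went from 34.4 ± 3.24 CPM to 1 read (n = 2 and 2). Ccnd2 stood at 59.4 ± 17.7 CPM and then had 2 reads, and Ldha fell from 245 ± 39 to 15 ± 3.29 CPM. Ddx4 rose from 15.9 ± 7.77 to 55 ± 7.2 CPM, the piRNA genes Fkbp6 from 2.45 ± 0.22 to 47.8 ± 11.3 and Piwil2 from 8.39 ± 3.27 to 53.2 ± 23.4. Rhox6 rose from 110 ± 16.1 to 1410 ± 348, Dppa3 from 611 ± 51 to 1385 ± 400 and Dppa2 from 34.2 ± 17.6 to 97.2 ± 18.6. Meg3, an imprinted non-coding RNA, fell from 198 ± 28.7 to 10.9 ± 4.19 CPM and Cdkn1c from 51.9 ± 4.55 to 10.5 ± 5.87. Prdm1 did not pass (145 ± 17.4 and 115 ± 72.9).

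In edgeR, 429 genes rose and 298 fell, against 97 and 92 in a fit of d4 and d4c5 alone and 756 and 609 with limma. Of 16 immediate early genes 4 fell, with Egr1 going from 24.1 ± 1.58 to 2.64 ± 2.84 CPM (6 adjusted over the list alone; adjusted p = 5.44e-05). Of 18 GDNF and FGF response genes 6 fell (9 adjusted over the list alone; adjusted p = 2.11e-07). Of 22 piRNA genes 5 rose (6, with 1 falling, adjusted over the list alone; adjusted p = 0.000308, but 0.0814 with an estimated correlation). Of 20 core germ cell genes 3 rose (6 adjusted over the list alone; 0.000308, then 0.0814). Of 12 p53 target genes 3 rose (4 adjusted over the list alone; 0.000598, then 0.0814). Of 18 glycolysis genes 3 fell (0.000598, then 0.368). Of 14 differentiation genes 5 rose and 1 fell (0.0371, then 0.365) and of 34 meiotic genes 4 rose (0.0335, then 0.397). Without the libraries of the second spike-in profile, here 1 of d4c5, 6 p53 target genes, 1 meiotic gene and 3 differentiation genes rose. With 2 libraries a side the count of all genes ranged from 413 to 1018 when single libraries were left out.

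Set against prospermatogonia, prospermatogonia-like cells had more transcripts of proliferation and early genes, though far fewer of these were called without m0 and m3. Mki67 was 179 ± 125 CPM against 21.2 ± 4.08, Rrm2 75.9 ± 79.3 against 5.47 ± 1.51 and Spc24 74.6 ± 48.1 against 3.73 ± 2.83 (n = 8 and 10). Nanog stood at 72.7 ± 75.3 CPM against 11.2 ± 7.78, Dppa5a at 1685 ± 1500 against 199 ± 191 and the interferon-induced Ifitm3, also a gene of early germ cells, at 353 ± 333 against 19.7 ± 22.7. Lower were Dnmt3l (145 ± 178 against 560 ± 202 CPM), Spocd1 (179 ± 215 against 400 ± 159) and Mael (569 ± 530 against 1777 ± 342). At m0 and m3 each of them stood far below its level at m5 or m7, which weighs on these means. Also lower were Gtsf1 (150 ± 166 against 438 ± 92.8), Ddx4 (433 ± 199 against 807 ± 212) and the neuropeptide gene Gal (6.84 ± 7.85 against 56.8 ± 21). Stra8 was higher in culture, 170 ± 163 CPM against 6 ± 2.02, and the translation gene Eif3j2, which has close relatives in the genome, was lower at 1.81 ± 1.51 against 72.5 ± 8.36.

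In edgeR, 1944 genes were higher and 4212 lower in culture, and without m0 and m3 1098 were higher and 1406 lower. Of 29 proliferation genes 19 were higher (8 without m0 and m3; adjusted p = 2.26e-18). Of 20 PGC genes 12 were higher and 1 lower (1 and 0 without; adjusted p = 7.5e-05). Of 22 piRNA genes 15 were lower (1 higher and 4 lower without; adjusted p = 2.58e-07) and of 19 cholesterol genes 7 higher (adjusted p = 5.32e-05). Of 20 core germ cell genes 1 was higher and 13 lower (2 and 2 without; adjusted p = 0.00012, but 0.0612 with an estimated correlation). Of 17 Sertoli markers 9 were higher (8 and 1 lower without; 0.00144, then 0.14). Of 44 oxidative phosphorylation genes 10 were higher (9.48e-09, then 0.0782). Of 18 glycolysis genes 5 were higher (0.0296, then 0.506) and of 9 endothelial markers 7 lower (0.0388, then 0.14). Adjusted over the list alone no count changed. Clu, a Sertoli gene, stood at 392 ± 135 CPM against 97.6 ± 39.9 and Inha at 103 ± 43.9 against 18.6 ± 11.6, while Hba-a1 of blood was nearly absent from the cultures (0.944 ± 1.45 against 31.2 ± 15.6).

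Spermatogonia-like cells differed from spermatogonia in part of their germ cell genes and in somatic transcripts. Ddx4 (484 ± 98.8 against 676 ± 78.3 CPM), Cd9 (216 ± 78.4 against 256 ± 124) and Dppa3 (9.46 ± 6.04 against 7.77 ± 5.74) did not pass. Dazl was lower (631 ± 329 against 1400 ± 363), as were Zbtb16 (26.7 ± 9.55 against 69.9 ± 33.4), the cadherin Cdh1 (14.4 ± 4.83 against 60.4 ± 31.3) and Dnmt3b (48.9 ± 11.1 against 120 ± 77.6; n = 6 and 10). Higher were the macrophage genes Lyz2 (73.8 ± 48.2 against 0.715 ± 1.03 CPM), Trem2 (34.6 ± 23.9 against 0.334 ± 0.538) and Apoe (631 ± 414 against 11.4 ± 8.1). So were the Sertoli genes Clu (351 ± 107 against 37.2 ± 16.3) and Inha (81.5 ± 34.2 against 12.8 ± 6.77) and the stromal genes Dcn (96.9 ± 61.8 against 3.57 ± 3) and Sparc (164 ± 33.7 against 16.3 ± 6.74). The stress genes Atf3 (16.4 ± 10.2 against 3.5 ± 3.62), Jun (16.2 ± 5.3 against 3.31 ± 1.4) and Cdkn1a (58.1 ± 17 against 20.2 ± 11.9) were also higher. Bcl6b, induced by GDNF, was higher at 81.4 ± 20.4 against 43.8 ± 27.9, and Eif3j2 (1.3 ± 0.701 against 46.3 ± 9.12) and Cap1 (19.6 ± 8.27 against 71 ± 8.34) were lower.

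In edgeR, 1091 genes were higher and 620 lower in culture, and fewer were called with time points as units. With the spike-in profile as a covariate 816 were higher and 248 lower, and only 751 of the 1711 calls were kept, so the genes and lists here may carry that technical split. Without both P1 libraries 2098 were called. Of 17 Sertoli markers 12 were higher (adjusted p = 4.51e-10). Of 16 stromal markers 10 were higher (adjusted p = 5.81e-06). Of 16 immediate early genes 6 were higher (adjusted p = 1.66e-05). Of 10 interferon response genes 3 were higher and 1 lower (adjusted p = 0.00448). Of 14 macrophage and blood markers 9 were higher and 4 lower (adjusted p = 0.000151, but 0.205 with an estimated correlation), and camera moved the proliferation list with none of its 29 genes passing in edgeR (adjusted p = 0.00216, and 0.336 with an estimated correlation). Of 28 genes of undifferentiated spermatogonia 1 was higher and 6 lower (adjusted p = 0.198), and of 34 meiotic genes 1 was higher and 5 lower (adjusted p = 0.465). Of 20 core germ cell genes Dazl alone was lower, and of 22 piRNA genes 2 were lower. Adjusted over the list alone the counts were the same.

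**Figure D3:**
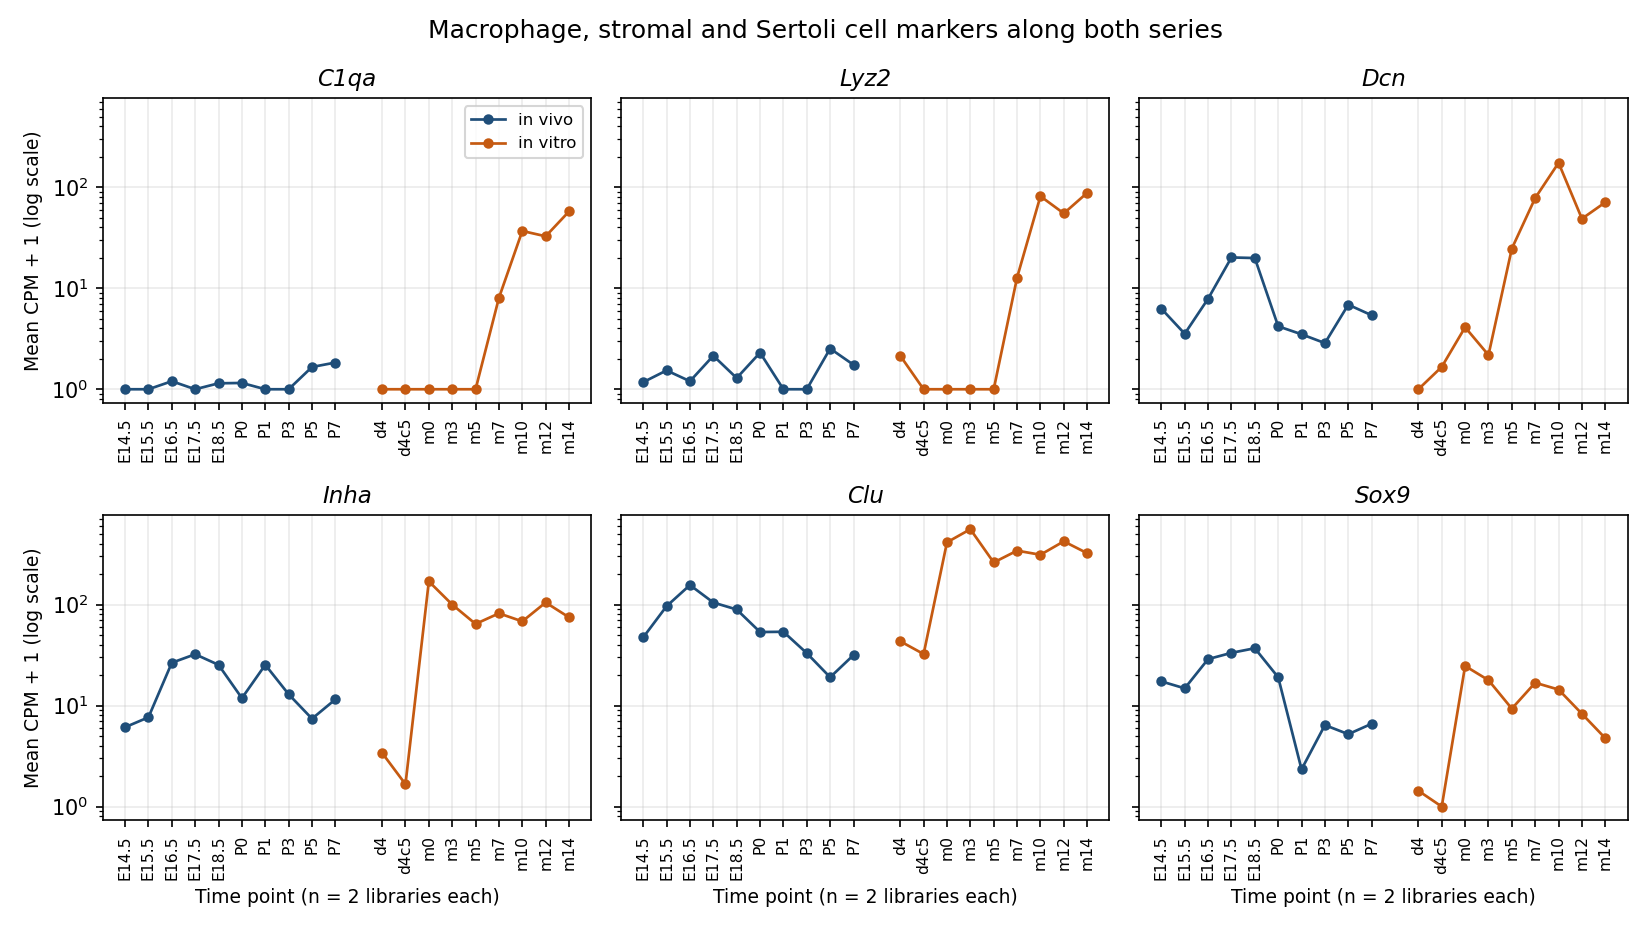
Markers of macrophages, stroma and Sertoli cells at each time point (n = 2 libraries per point, log scale of CPM + 1). C1qa was 0 up to m5 and 56.5 CPM at m14, and Clu stood at 31.3 CPM at d4c5, 411 at m0 and 321 at m14.

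Several somatic transcripts of m14 were lower or without reads in the GSC-like lines. Fcrls of macrophages went from 52.1 ± 11.6 CPM to 0 reads in 16 libraries (at least 870-fold) and Csf1r from 28.3 ± 7.02 CPM to 1 read (n = 2 and 16). The Sertoli genes Cst12 and Nr5a1 went from 16.2 ± 16.1 and 8.77 ± 0.806 CPM to 0 reads (at least 270-fold and 147-fold), and Dcn fell from 69.8 ± 8.31 to 7.04 ± 4.55. Dazl rose from 559 ± 6.99 to 1723 ± 135 CPM and Sycp1 of the synaptonemal complex from 70.9 ± 4.75 to 284 ± 48.4. Stra8 fell from 191 ± 17.8 to 53.3 ± 14.2, Sohlh1 from 82.1 ± 19.3 to 32 ± 15 and Kit from 47.4 ± 3.61 to 23.1 ± 6.05. Of the glycolysis genes Ldha rose from 39 ± 8.94 to 266 ± 82.7 CPM and Slc2a1 from 23.2 ± 2.15 to 95.9 ± 57.8. Of the cholesterol synthesis genes Mvk fell from 46 ± 0.289 to 6.64 ± 2.55 and Mvd from 60.2 ± 21.1 to 12.6 ± 3.18. Zic1 stood at 70.1 ± 26.6 CPM in the lines and had 1 read at m14, and Mpzl2 rose from 4.26 ± 0.573 to 71.75 ± 14.53. Ddx4 (487 ± 73.2 and 630 ± 62.2 CPM) and Cd9 (178 ± 20.4 and 254 ± 45.1) did not pass.

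In edgeR, 712 genes rose and 1550 fell, but with lines as units only 56 rose and 243 fell. Both m14 libraries have the second spike-in profile and all line libraries the first, so this comparison cannot part the cells from that technical split. Of 17 Sertoli markers 14 fell (adjusted p = 4.16e-16). Of 14 macrophage and blood markers 10 fell (adjusted p = 2.22e-11) and of 19 cholesterol genes 8 fell (adjusted p = 1.1e-07). Of 18 glycolysis genes 8 rose (adjusted p = 1.85e-08, but 0.182 with an estimated correlation). Of 16 stromal markers 7 fell (0.0218, then 0.224). Of 34 meiotic genes 6 rose and 2 fell (0.0218, then 0.414). Of 18 GDNF and FGF response genes 5 rose and 1 fell (0.0213, then 0.262). Of 44 oxidative phosphorylation genes Atp5d fell (1 more rose adjusted over the list alone; 0.023, then 0.58). Adjusted over the list alone the other counts here were the same.

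GSC1 differed from P7 spermatogonia in genes of differentiation, of the GDNF and FGF response and of glycolysis. Stra8 fell from 295 ± 38.4 to 35.2 ± 5.98 CPM, the receptor gene Kit from 244 ± 29.5 to 27.6 ± 0.958, Dmrtb1 from 142 ± 21.6 to 24.3 ± 1.67 and Dnmt3b from 246 ± 45.2 to 62.1 ± 8.91 (n = 2 and 2). The stem cell genes T (7.11 ± 0.205 to 74.4 ± 1.32), Etv4 (7.72 ± 0.652 to 59.7 ± 0.0657) and Spry4 (5.38 ± 0.105 to 48.9 ± 3.98) rose. So did Ldha (13.5 ± 1.07 to 184 ± 2.97), Slc2a3 (13.5 ± 0.659 to 229 ± 12.5), Zic1 (1.43 ± 0.739 to 166 ± 6.73) and the imprinted growth factor Igf2 (17.1 ± 3.12 to 143 ± 7.96). Hoxb5 went from 0 reads to 21.3 ± 0.245 CPM (at least 48.9-fold) and Bcl3 from 0 reads to 20.6 ± 6.63 (at least 47.3-fold), while Cited1 fell from 114 ± 1.05 to 1.14 ± 0.845. Ddx4 did not pass (654 and 645 CPM).

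In edgeR, 1119 genes rose and 1164 fell, in 1 line against 1 age. With lines and time points as units each side would hold a single sample, so variation between GSC lines or between time points was not measured. The risers were the more under RPM scaling (1243 and 1016), which shifts every fold by 0.082 log2. They were also the more under median-of-ratios scaling (1189 and 1074) and DESeq2 (1124 and 1018). Of 14 differentiation genes 1 rose and 7 fell (9 adjusted over the list alone; adjusted p = 8.05e-07). Of 18 GDNF and FGF response genes 13 rose (adjusted p = 3.58e-11). Of 18 glycolysis genes 10 rose (adjusted p = 6.58e-15). Of 16 immediate early genes 6 rose (7 adjusted over the list alone; adjusted p = 4.94e-06) and of 10 interferon response genes 4 rose (adjusted p = 0.000193). Of 28 genes of undifferentiated spermatogonia 13 rose and 5 fell (adjusted p = 0.00189, but 0.154 with an estimated correlation). Of 22 piRNA genes 6 fell (0.000114, then 0.0521) and of 17 Sertoli markers 1 rose and 6 fell (0.00189, then 0.154). Of 16 stromal markers 4 rose (0.0156, then 0.154), and of 14 macrophage and blood markers 4 fell (0.0272, then 0.422). Adjusted over the list alone those 5 and the GDNF, glycolysis and interferon counts did not change.

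In GSC-like lines W and S against GSC1, Ddx4 (644 ± 49.9 against 660 CPM) and Cd9 (260 ± 40.4 against 325) did not pass, but several stem cell genes were lower than in that 1 line. T stood at 13.5 ± 4.46 CPM against 76.1, Tcf15 at 15.2 ± 4.93 against 98.6, Pax7 at 0.5 ± 0.59 against 11.2, Eomes at 1.29 ± 1 against 14.499 and Lin28a at 2.9 ± 0.69 against 9.48 (8 lines against 1 line). Higher were the MAP kinase phosphatase gene Dusp6 (191 ± 15.6 against 47.1 CPM), Sycp1 (290 ± 31.1 against 116), Pdha2 (74.1 ± 7.65 against 32.7) and Magea8 (85.6 ± 15.1 against 10.9). Eif3j2 (0.84 ± 0.413 against 44.7), Cap1 (3.6 ± 1.2 against 78.8), Etv4 (26.2 ± 6.86 against 61) and Wt1 (6.99 ± 2.51 against 26.6) were lower too. Not all of these differences part GSC-like cells from GSC1. In the prefix-16 GSC-like lines, left out here, Eif3j2 (45.9 CPM), Cap1 (78.5) and Pdha2 (32.6) stood near GSC1, and Wt1 (17.1) stood between. The W and S lines also differ from GSC1 in transgene reads, given below.

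In edgeR on reads summed by line, 266 of 12106 genes were higher and 285 lower. Leaving out the first or second GSC1 library left 346 or 347 called in all. Of 26 genes of undifferentiated spermatogonia 7 were lower (camera adjusted p = 0.00476, but 0.469 with an estimated correlation). Of 18 cholesterol genes 1 was lower (adjusted p = 6.03e-06, then 0.469), counts that stayed the same adjusted over the list alone. None of the oxidative phosphorylation genes passed in edgeR, with a camera shift (adjusted p = 0.00192) lost at the estimated correlation (0.519). A single GSC line stood on that side, so its spread was taken from the other lines and variation between GSC lines was not measured.

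Few genes differed at least 2-fold between S and W lines (206 of 12106), though 2509 had an edgeR adjusted p below 0.05 at any fold. Sall1, a zinc finger gene active in stem spermatogonia, stood at 5.92 ± 1.91 CPM in S lines against 25.6 ± 7.18 in W lines, and Nanos3 at 9.53 ± 2.64 against 20 ± 2.63 (n = 4 and 4 lines). Also lower were Atp5k at 63.1 ± 2.74 against 181 ± 26.5, Ndufa3 at 40.5 ± 1.19 against 115.4 ± 15.54, Hnrnpl at 29.6 ± 1.03 against 84.6 ± 17.2 and Bola2 at 27.5 ± 4.98 against 86.8 ± 13.8. Higher in S lines were Dact1 (65.7 ± 4.25 against 30.7 ± 6.95 CPM), Cd109 (22.1 ± 7.19 against 8.51 ± 1.87) and Glmp (25.8 ± 12.9 against 9.24 ± 4.18). Ddx4 (684 ± 24.8 against 604 ± 30.4) and Cd9 (241 ± 40.9 against 279 ± 34.2) did not pass.

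In edgeR, 48 genes were higher and 158 lower in S lines, or 74 and 115 under RPM scaling. The oxidative phosphorylation list leaned downward by camera (adjusted p = 1.62e-14), and the lean was lost with the estimated correlation (adjusted p = 0.121). None of its 44 genes reached a 2-fold change in edgeR. Ndufc1 and Ndufb2 came closest, both 1.89-fold lower (edgeR adjusted p = 2.67e-07 and 6.69e-07). The same loss met an upward lean of proliferation genes (none passing; 0.00333, then 0.279) and a downward one of differentiation genes (Nanos3 lower, 3 adjusted over the list alone; 0.0163, then 0.131).

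The prefix-16 W lines stood apart from the other W lines in genes of several kinds. Eif3j2 was 45.9 ± 3.55 CPM against 0.908 ± 0.577 and Cap1, of actin turnover, 78.5 ± 8 against 4.35 ± 1.31 (n = 3 and 4 lines), as in GSC1. Sfi1 was 440 ± 72.7 against 51.8 ± 24.8, Thg1l 30.4 ± 1.67 against 4.91 ± 1.47 and Glmp 64.5 ± 14.6 against 9.24 ± 4.18. Foxa2 was also higher (24.4 ± 8.33 against 3.78 ± 1.91 CPM). Lower were Pou5f1 (2.94 ± 2.41 against 25.5 ± 5.16 CPM), Sohlh1 (8.98 ± 7.7 against 44.1 ± 5.38), Tdrd9 of the piRNA pathway (8.52 ± 8.41 against 49 ± 5.63) and Pdha2 (32.6 ± 7.84 against 76.5 ± 7.51). Imprinted Mest (150 ± 23.1 against 41.2 ± 2.12), Grb10 (22.4 ± 9.76 against 5.11 ± 0.174) and Phlda2 (29.5 ± 18.3 against 7.08 ± 1.84) were higher, and Ddx4 did not pass (536 ± 20.6 against 604 ± 30.4).

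In edgeR, 251 genes were higher and 146 lower. Of 22 imprinted genes 5 were higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.158), and no list shifted as a whole. Transgene sequences parted the lines as well: RBG_pA had 88 to 1606 reads in all 8 libraries of GSC1 and the prefix-16 lines and at most 1 in 16 W and S libraries. BGH_pA had 7 to 51 in W and S libraries and at most 1 in those 8. BGH_pA was also present in vivo (30 to 192 reads) and from d4 to m14 (24 to 187), and SV40_pA was present from d4 to m14 only in quantity (23 to 6933 reads). Eif3j2 stayed at or below 2.9 CPM from d4 to m14 and at 34 or above in vivo.

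**Figure D4:**
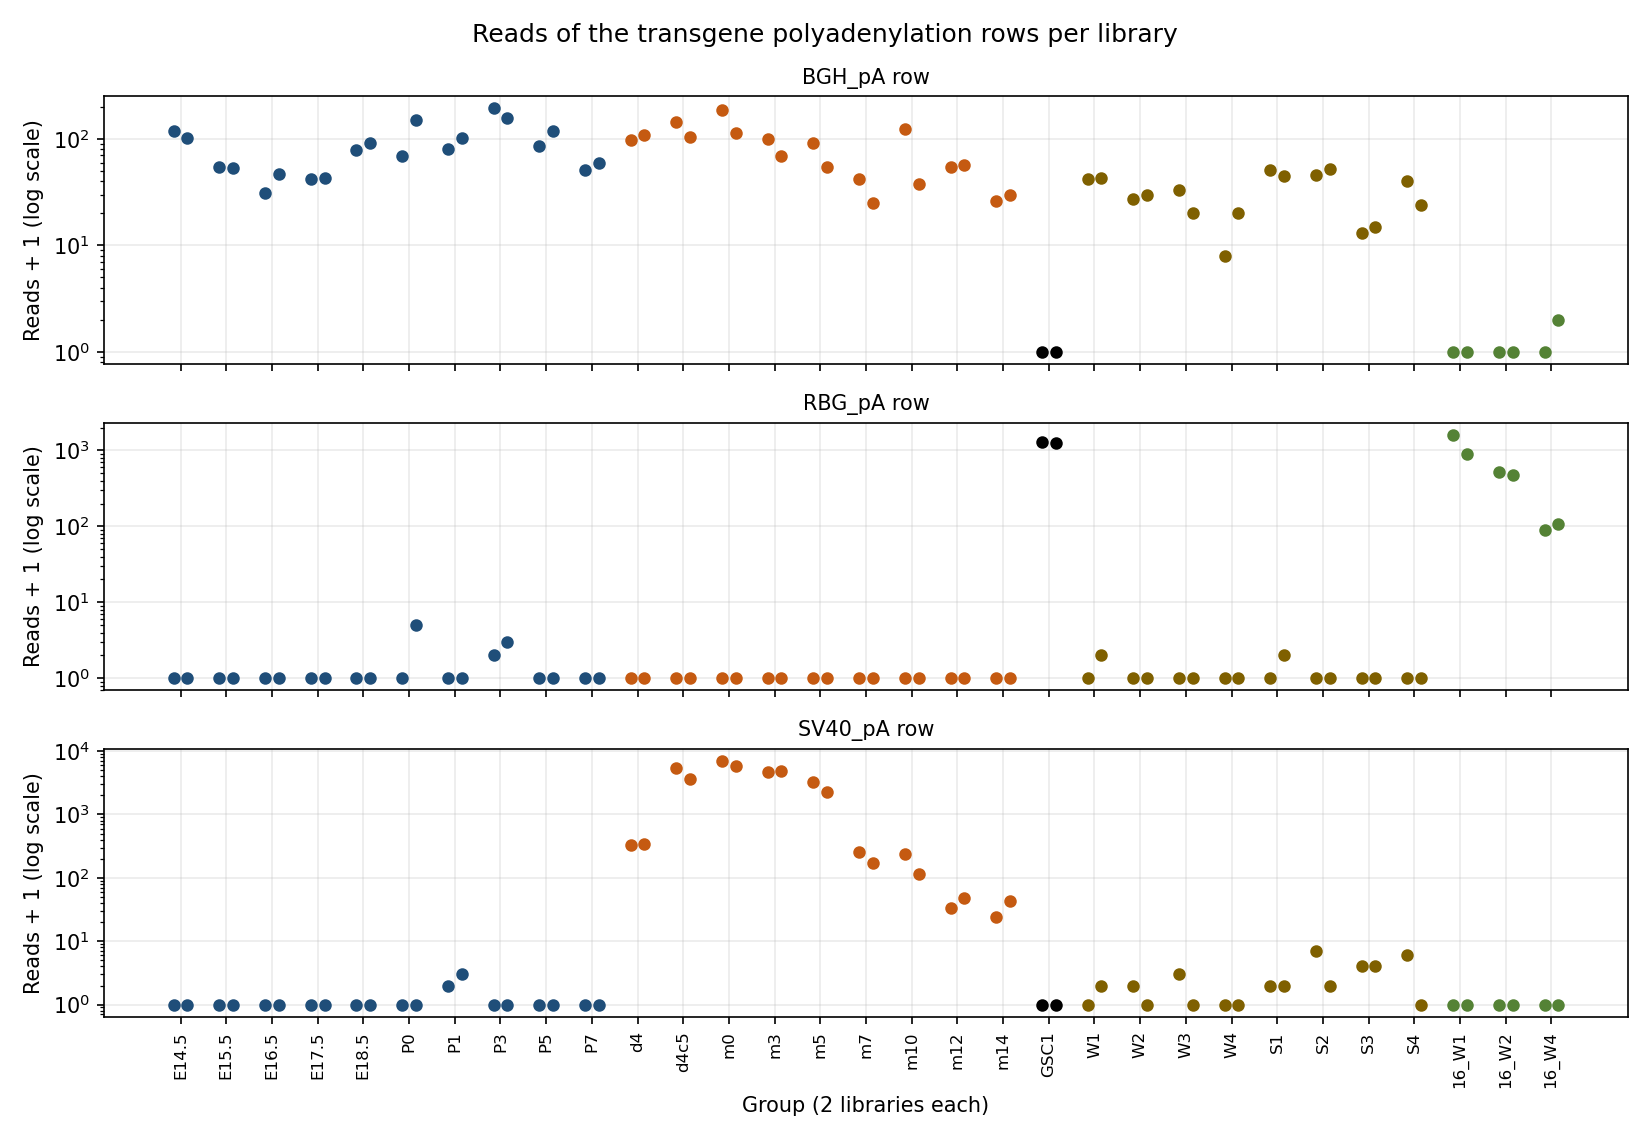
Reads of 3 transgene polyadenylation sequences in each of 62 libraries (log scale of reads + 1). RBG_pA had 88 to 1606 reads in GSC1 and prefix-16 libraries and at most 1 in the other GSC-like libraries, where BGH_pA had 7 to 51.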

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

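For the tests in this part, those on macrophage and Sertoli markers, on parental genotype and on other splits of the samples were written before their results were seen, and those on the share of germ cells, on m0 and m3, on scaling and on batch were written after. Between culture and development 4209 genes changed by different amounts, among them Spocd1 (6.06), Piwil4 (4.48), Gtsf1 (3.56), Tyrobp (6.5), Stab1 (6.33), Mki67 (−2.6), Rrm2 (−3.11), Spc24 (−3.83) and Syce2 (−2.51), given as differences of log2 fold changes. Whole lists differed too, with medians of −1.27 for PGC and pluripotency genes, 1.33 for core germ cell genes, 1.69 for piRNA and methylation genes, −1.33 for proliferation genes, 2.76 for stromal markers, 6.11 for macrophage and blood markers and −0.85 for cholesterol synthesis genes.

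The proliferation and piRNA differences were set against m0 and m3, which stand within the prospermatogonia-like stage and resemble E14.5 less (correlations of 0.513 and 0.584) than m5 (0.808) and m7 (0.614) do. Without m0 and m3, 3 of 20 proliferation genes and 0 of 14 piRNA genes were still called, so the difference may come from where these cultures are placed on the time line. Another scaling of the libraries does not account for it: at the least 90% of the called genes stayed called under RPM or median-of-ratios scaling (18 of 20 and 14 of 14).

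The somatic markers from m7 to m14 were tested for moving together between the 2 libraries of a group. The 12 macrophage and blood markers had a mean pairwise correlation of 0.675 in 8 libraries, above 100% of 1000 random lists of like expression (median −0.014, 95th percentile 0.129). Macrophages or their RNA in the sorted cells would give this. Deviations within a pair mirror each other, so each correlation rests on a single difference per group. At m7 and m10 the libraries of a pair also differ in spike-in profile, a split that the test does not separate. The Sertoli markers reached 0.096, at percentile 95.1, barely above the 95th percentile of 0.095, so Sertoli cells or their RNA could be present, in a share that this test does not measure. A lower share of germ cells that raises all somatic types alike would raise both lists. From m5 and m7 to m10–m14 the macrophage median rose by 3.48 log2 while the Sertoli median was −0.25 and the Sertoli upper quartile only 0.14. These values argue against an equal rise of the 2 lists. They do not exclude a lower share of germ cells, because the test takes marker levels within a cell type as constant.

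Transgene sequences differed between groups, also between lines that share a genotype label. BGH_pA reached 192 reads in vivo, RBG_pA 1606 reads in GSC1 and prefix-16 libraries, and SV40_pA 6933 reads between d4 and m14. All cultured lines carry the same genotype label, Acr-EGFP and Actin-EGFP. Another parental genotype of the W and S lines than the labels state is a hypothesis that was tested on genes. The change from W to prefix-16 lines and from S lines to GSC1 correlated across 12106 genes (Pearson 0.232, Spearman 0.2, genes not being independent replicates). Of 101 genes called in both 71 went the same way, 45 higher where independence gives 8.1 and 26 lower where it gives 4. Another 30 went opposite ways, for which the number under independence was not computed. The Pearson correlation lay only just above the 0.2 set beforehand. The transgene reads themselves do not rest on that correlation. RBG_pA was read in GSC1 and the prefix-16 lines and hardly in W and S lines. BGH_pA went the other way, with 7 to 51 reads in W and S libraries and at most 1 in GSC1 and prefix-16 libraries. The transcribed transgene sequences thus differed between these lines, which their shared label does not show. A wider shared genotype of GSC1 and the prefix-16 lines is possible but not proven. A shared batch alone does not account for at least 88 RBG_pA reads in each of their libraries with at most 1 in W and S libraries. That test was written on the same reads that raised the question. For the genes that changed alike a shared batch was not tested.

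Other splits of the same time points or lines asked whether a random grouping could give as many calls. For lines the real split gave the most calls, both for S against W (1 of 35; 206, highest other 2) and for prefix-16 against W (1 of 35; 397, highest other 61). Time points differ from each other, so their other splits also hold real differences and can neither exclude chance nor show it. In vivo 4 of 100 splits gave at least the real 5248 (highest other 6001). For prospermatogonia-like cells against prospermatogonia 3 of 100 did (6156, highest other 6717). The highest splits of these comparisons put E14.5 apart from E15.5 to E18.5. Likewise 7 of 35 splits did so in vitro (2920, highest other 4086) and 9 of 100 for the difference of the steps (4209, highest other 5952). For spermatogonia-like cells against spermatogonia 16 of 56 gave at least the real count (1711, highest other 4612). There the highest split set m10, P0 and P1 apart, and in vitro it set m5, m7 and m10 apart, so structure of the samples other than their groups stays open. For PGC-like against prospermatogonia-like cells (2 of 15; 3590, highest other 6985) the splits are too few to tell.

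Among the lines of a set, 4 of 44 list means stood apart from the other 3 lines by the ratio of Dixon, where chance gives about 1 in 20 groups, or 2.2 here. They were immediate early genes in W4 (mean log2 CPM 5.3 against 5.19 to 5.21, ratio 0.848), GDNF and FGF response genes in W1 (5.78 against 5.62 and 5.63, ratio 0.947), CDK inhibitors in S2 (3.52 against 3.79 and 3.84, ratio 0.867) and imprinted genes in S4 (4.7 against 4.69 for the nearest line, ratio 0.985, a high ratio from a gap of about 0.01).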

How the results depend on the processing

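Of 6382 repeats of 219 genes by comparison, 6191 kept direction and side of the threshold, 191 kept direction only and 0 reversed. Named genes were chosen largely for the size of their change in these same data, which favours such stability. The counts were less stable, and the causes were not tested unless stated.

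With limma and a pseudocount of 5, which shrinks low levels by construction, counts fell to 1991 in vivo, 1126 in vitro, 1800 for the difference and 1997 for PGC-like to prospermatogonia-like cells. They fell to 2546 and 435 for the like stages, 853 against m14, and 1083 for GSC1 against P7, and to 221 against GSC1, 29 for S against W, 122 for prefix-16 lines and 341 for the overlap. With a pseudocount of 0.5 there were 5422 for PGC-like to prospermatogonia-like cells and 1526 for d4c5 against d4, and with limma at 1 there were 1365 for the latter and 119 for S against W. A filter of 20 RPM, which tests fewer genes, left 2931 in vivo, 1847 in vitro, 3563 and 929 for the like stages, 1505 against m14, 262 against GSC1, 66 for S against W and 151 for prefix-16 lines, and no filter gave 337 for S against W.

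With time points or lines as units, and so fewer samples, 1049 genes were called in vitro, 520 for the difference, 1292 for PGC-like to prospermatogonia-like cells, 664 for spermatogonia-like cells, 299 against m14 and 65 for GSC1 against P7. A fit of d4 and d4c5 alone called 189 genes. Libraries as units called 594 for prefix-16 lines, and 597 with a replicate block, that is a pairing by library number. Added after the data were seen: libraries numbered 1 or 2 alone called 71 and 36 in vitro (fewer samples), leaving out m0 and m3 gave 1231 for the difference, 2504 for prospermatogonia-like cells and 1866 for the overlap, and the spike-in covariate gave 1064 for spermatogonia-like cells.

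Of 273 list and comparison pairs camera called 99, 42 with an estimated correlation and 168 with fry, and 21 of 42 nearest stages stayed with Spearman correlation.

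With each library, or for the line sets also each line, left out in turn, a lone remaining library being taken to vary like the other groups, counts ranged over 4979–5347 in vivo, 2706–2965 in vitro, 3787–4273 for the difference, 3204–3607 for PGC-like to prospermatogonia-like cells, 413–1018 for d4c5 against d4, 5848–6276 and 1281–2107 for the like stages, 1557–2291 against m14, 1671–1809 for GSC1 against P7, 346–579 against GSC1, 159–226 for S against W and 293–559 for prefix-16 lines. The d4 and d4c5 count moved more than 1.5 times without the first d4c5 library (413) or the second d4 library (481), and that against GSC1 without its first (346) or second library (347). Depth limits genes below 5 RPM, which were not tested.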

Other observations

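Some meiotic genes stood high at m5 or m7 of the culture. Stra8 went from 2.06 CPM at m0 to 177 at m3, 394 at m5 and 106 at m7, before 58.9 at m10 and 191 at m14, whereas in vivo it was 3.45 to 8.44 from E14.5 to E18.5 and 295 at P7. Sycp3 stood at 434 CPM at m5 against 115 to 297 in prospermatogonia, Spo11 at 78.7 at m5 against 28.7 to 44.5, and Meiob at 33.2 at m7 against 4.41 to 11.7. Without m0 and m3, 14 of 34 meiotic genes were higher and 1 lower in prospermatogonia-like cells than in prospermatogonia, but with them 6 were higher and 9 lower. These genes were chosen after their values were seen.

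SV40_pA followed Dppa3 along the culture, with its largest reads between d4c5 and m5 while Dppa3 stood at 1385 CPM at d4c5, 1571 at m0, 1824 at m3 and 1097 at m5, and both were low at m14 (Dppa3 4.57 CPM). Cap1 stood between 43 and 79.3 CPM in vivo, at 0.981 to 22.9 from d4 to m14 and at 77.1 in GSC1. EF1a sequences had reads in all libraries and piggyBac had 0.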
